A study of Homo sapiens with 6 samples.

How the data were processed

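Total RNA of FACS-sorted MDA-MB-231 cells was sequenced by the submitters after ribosomal RNA depletion, fragmentation and random priming, per the labels' protocols. The labels name 2 groups, FABP4 binding and FABP4 non-binding, with 3 libraries each, and columns were matched to samples by the column names that the labels give. The deposited values are TPM, from the values themselves, since each of the 6 columns sums to 1000000 over 58051 Ensembl genes. The genome build was hg38, per the submitters' processing notes. The aligner, the quantification tool, the gene annotation and any filter on reads are not given in the sources used here. TPM keep no depth, so the precision that depth gives is unknown, no interval or floor was computed and no count model was run. Whether replicates are separate cultures or sorts is not stated in the labels.

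TPM divide by transcript length and by the sum over all genes, which affects the measurements in several ways. A transcript class that takes more of a library lowers every other class. Reads that match a gene and its processed pseudogenes may have been divided, given to 1 of them or dropped, which moves the levels of genes with many copies. The median log2 change over all tested genes was 0.36, and alternatives that shift it are given in the text.

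The design was fixed before the data were examined and named a count test for counts and limma for normalized units. Since the values are TPM, limma was used. Genes with at least 1 TPM in at least 3 libraries were kept (15574 genes) and log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3 with an intensity trend, no covariate and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Gene lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists with at least 5 tested genes), with an estimated correlation and with fry as alternatives. Shares of TPM were compared with an exact two-sided permutation test, whose smallest p is 0.1 for 3 against 3. Of the gene identifiers, 98.1% had a symbol in the reference name table and 99.0% were in GENCODE release 29, which supplied gene types, hg38 coordinates and transcript features. Its annotation may not be the one the submitters used.

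The 41 lists were fixed before the data were examined and held 1115 gene entries, 5 of which had no match: mitochondrial genome transcripts; oxidative phosphorylation, nuclear encoded; integrins and focal adhesion; fatty acid oxidation; heat shock and chaperones; replication-dependent histones; luminal, basal, leukocyte, fibroblast, endothelial and adipocyte markers; glycolysis, antioxidant and NRF2 targets, G1/S and DNA replication, G2/M and mitosis, lipid droplet and triglyceride storage, cell surface glycosaminoglycan and syndecan, interferon-stimulated, matrix proteases and inhibitors, lysosome and endocytosis, desmosome and cell junction, fatty acid binding and uptake, fatty acid synthesis and desaturation, cholesterol synthesis, protein kinase C family and adaptors, stemness and aldehyde dehydrogenases, nuclear-retained and long noncoding RNA, cytosolic ribosomal proteins, ATF4 and unfolded protein response, mesenchymal, p53 targets, immediate-early and dissociation response, NF-kB inflammatory targets, NADPH oxidases and oxidant producers, invadopodia and actin remodelling, structural RNA left after depletion, IL6 and STAT3 targets, epithelial, hypoxia, and translation and ribosome biogenesis. Lists of epidermal differentiation, simple epithelial, hair and other keratins, mucins and secreted barrier proteins, and laminins and hemidesmosome were added after the values were seen, so they are described by counts of their members and no list test is given for them.

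Named genes followed a rule fixed before the data were examined: 15 genes tied to the study's question, whatever they showed; the 8 largest rises and 8 largest falls among genes past the threshold with groups that did not overlap and a mean of at least 1 TPM; and the 3 members with the smallest p in the list's direction in each of the 8 lists with the smallest p. Among the largest rises and falls the rule left out names of noncoding genes, and the GENCODE protein-coding type was applied in addition. List members were not filtered by type, so the ribosomal RNA MT-RNR2 is among the named genes. The rule gave 52 genes in all. Other genes named in the text were chosen after their values were seen.

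The scripts were tested on simulated values for the 15574 genes and 6 libraries of this comparison. With 200 genes changed 2-fold, 15 (7.5%) were recovered, 14 of them among 68 genes at 20 TPM or more, with 1 false call, and no call was made with nothing changed. Of 41 lists, all 5 shifted by 0.7 log2 were called and none of the others. The simulated genes varied independently of each other, so this run cannot show false list calls that come from correlation between genes. The real comparison called 4156 genes, so its adjusted threshold falls at a larger p. The 7.5% therefore does not measure the power of the real comparison. Alternatives fixed beforehand were the replicate number as a block, quantile normalization, no filter, a filter of 5 TPM, a pseudocount of 0.1, a 2-fold threshold, leaving out each library, an estimated correlation and fry. Added after the values were seen were a shift to a common median, rescaling over nuclear protein-coding genes, and removal of each library's trend with GC content. The rescaling also left out all other genes, so 12519 genes were tested and lists were set against these alone. Alternatives that need counts were not run. The result of 1 gene is not reported here.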

Results

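The data were RNA sequencing profiles of MDA-MB-231, an established human breast cancer line with a mesenchymal-like form. Cells had been exposed to fluorescently tagged recombinant human FABP4 and parted by flow cytometry into cells that bound the protein and cells that did not. FABP4 is a small carrier of fatty acids, best known from adipocytes and macrophages. Each subpopulation had 3 libraries, giving 6 in all, made from ribosomal RNA-depleted, randomly primed total RNA. Values were TPM, a length-corrected share of each library's transcripts, for 58051 genes. Each library summed to 1000000, so the sequencing depth behind a value is unknown and no counting interval can be given. Between 15300 and 15945 genes per library reached 1 TPM. Several RNAs that every cell makes were listed at 0, so a listed 0 is not read as absence, and genes with such values are given library by library. The labels do not say that the 3 libraries of a group came from separate cultures or sorts, so p-values measure only the spread between these libraries, which may be technical.

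The comparison asked how the transcriptome of cells that bind FABP4 differs from that of cells that do not. The series title ties it to invasion, protein kinase C and mitochondrial reactive oxygen species. Transcripts of the mitochondrial genome made up 10.5% ± 0.668 of TPM in the binding libraries and 3.14% ± 0.208 in the non-binding libraries (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). By limma, 31 of 53 nuclear genes of oxidative phosphorylation, 18 of 26 integrin and focal adhesion genes and 12 of 23 genes of fatty acid oxidation were higher in the binding cells. With every library shifted to a common median the counts were 11, 11 and 6, and with quantile normalization 17, 9 and 7. The camera calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.739 with an estimated correlation for each, Benjamini-Hochberg). PRKCA and the luminal keratins KRT8, KRT18 and KRT19 were also higher. The genes KRT1, KRT2, PKP1, HSPE1, AHSA1 and CRYAB were lower. Of 15574 genes tested with limma on log2(TPM + 1), 4156 passed a Benjamini-Hochberg adjusted p of 0.05, 3047 higher and 1109 lower in the binding libraries, and 1033 of them differed at least 2-fold (720 higher, 313 lower). The 2 groups did not overlap in 52.2% of tested genes, where chance gives 10% on average over all splits. Genes vary together, so a single chance split can lie far from 10%, and the share is no test.

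The median log2 change over all tested genes was 0.36, so changes of lists and of the main named genes are also given relative to it. When every library was shifted to a common median, 962 genes were higher and 1890 lower, or 33.7% higher against 73.3% without the shift. Quantile normalization gave 1197 higher and 1246 lower, or 49.0% higher. The number of calls depended on single libraries: it was 64 without non-binding replicate 3, 360 without non-binding replicate 2, 1938 without non-binding replicate 1, 2193 without binding replicate 3, 2724 without binding replicate 2 and 2863 without binding replicate 1. In each of these 6 fits all 4156 genes kept their sign, and without non-binding replicate 3, 3471 of them lay under an adjusted p of 0.1. Kept signs are a weak check, since these genes were chosen on all 6 libraries and each fit reuses most of them.

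All 15 tested transcripts of the mitochondrial genome, which encodes subunits of the respiratory chain and the RNAs of the mitochondrial ribosome, were higher in the binding cells, and all 15 also when adjusted over the list alone. Their median log2 change was 1.77, or 1.42 above the median of all genes. MT-CO3 (ENSG00000198938, mitochondrial genome 9207 to 9990, hg38), a subunit of cytochrome c oxidase, averaged 9549 ± 1004 TPM in binding and 2366 ± 155 TPM in non-binding libraries (SD, n = 3 each). Its log2 change was 2.01, or 1.65 relative to all genes (SE 0.13; limma, Benjamini-Hochberg adjusted p = 0.00086). MT-CO2 and MT-ND4 changed by 1.94 and 1.98 and the ribosomal RNA MT-RNR2 by 1.98 on the log2 scale. The list was higher by camera with Benjamini-Hochberg adjustment (adjusted p = 1.27e-13), a call lost with an estimated correlation (adjusted p = 0.667 with an estimated correlation). Without non-binding replicate 3, 14 of the 15 transcripts passed.

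Of 53 tested nuclear genes of oxidative phosphorylation, 31 were higher, 3 lower and 19 did not pass. Adjusted over the list alone, 40 were higher and 3 lower. The median log2 change was 0.66, or 0.30 above that of all genes (camera with Benjamini-Hochberg, adjusted p = 0.000275; adjusted p = 0.739 with an estimated correlation). CYC1, the cytochrome c1 subunit of complex III, averaged 311 ± 55.6 TPM against 166 ± 6.26 (SD, n = 3 each), a log2 change of 0.89, or 0.53 relative to all genes (SE 0.15; limma, Benjamini-Hochberg adjusted p = 0.0136). COX6C of complex IV changed by 1.07 and UQCRQ of complex III by 0.80 on the log2 scale. With the common median 11 members were higher and 3 lower, and with quantile normalization 17 and 2. Without non-binding replicate 3 none of the 53 passed, though the list did (camera adjusted p = 0.00032, within a range over all alternatives of 2.2e-08 to 0.739).

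PRKCA, which encodes the conventional protein kinase C alpha (ENSG00000154229, chromosome 17, 66302636 to 66810743), averaged 59.9 ± 5.55 TPM in binding and 25.4 ± 1.18 TPM in non-binding libraries (SD, n = 3 each), 2.36 times higher. The log2 change was 1.20, or 0.84 relative to all genes (SE 0.14; limma, Benjamini-Hochberg adjusted p = 0.00746). It was 0.88 with the common median and 0.95 with quantile normalization. All 3 binding libraries lay above all 3 non-binding libraries, but the call was narrowly lost without non-binding replicate 3 (log2 change 1.17; limma, Benjamini-Hochberg adjusted p = 0.0516). PRKCD, a calcium-independent isoform, averaged 70.8 ± 6.51 against 71.8 ± 1.41 TPM. PRKCE, of the same class, averaged 13.7 ± 7.19 against 7.49 ± 0.361 TPM. Neither passed (limma, Benjamini-Hochberg adjusted p = 0.898 and 0.124). In the list of protein kinase C family and adaptors, 5 of 19 tested genes were higher and none lower, 7 and 0 adjusted over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.114; adjusted p = 0.773 with an estimated correlation). Of these, 2 were higher and 1 lower with the common median, 4 and 0 with quantile normalization, and none of the 19 passed without non-binding replicate 3. The share of higher members lay near that of all tested protein-coding genes, 2824 of 12050. The list median was 0.08 above that of all genes. The list passed upward with fry (adjusted p = 0.027), which sets a list against no change.

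Among antioxidant genes and targets of the redox regulator NRF2, 15 of 32 tested genes were higher, 1 was lower and 16 did not pass. Adjusted over the list alone, 18 were higher and 1 lower. The median log2 change was 0.67, or 0.31 above that of all genes (camera with Benjamini-Hochberg, adjusted p = 0.0204; adjusted p = 0.739 with an estimated correlation). The call was also lost when TPM was rescaled over nuclear protein-coding genes, the only genes then tested, and without non-binding replicate 2. Higher members numbered 9 with the common median and 10 with quantile normalization, with 1 lower in each, and none of the 32 genes passed without non-binding replicate 3. The lower member was AKR1B10, an aldo-keto reductase, at 6.32 ± 2.61 TPM in non-binding and 1.95 ± 1.24 TPM in binding libraries (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.0477), a call lost without any 1 of non-binding replicates 1, 2 and 3 or binding replicates 2 and 3. It was also lost without a filter, with a pseudocount of 0.1 and with the GC trend removed. SOD2, the manganese superoxide dismutase of mitochondria, averaged 18.0 ± 3.53 against 16.7 ± 1.59 TPM (adjusted p = 0.732 by limma with Benjamini-Hochberg), a log2 change of 0.09 that turned to -0.23 with the common median and with quantile normalization. Of 11 tested NADPH oxidases and other oxidant producers, 2 were higher and none lower, also when adjusted over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.582). For that list the median log2 change was 0.05, or -0.31 relative to all genes, and the camera direction was down. The median was -0.27 with the common median, 0.15 without binding replicate 1, where the direction turned up, and 0.18 without non-binding replicate 3.

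Integrin and focal adhesion genes were higher in the binding cells, 18 of 26 tested with none lower and 8 not past the threshold. Adjusted over the list alone, 20 were higher, with the common median 11 and with quantile normalization 9. The median log2 change was 0.76, or 0.40 above that of all genes (camera with Benjamini-Hochberg, adjusted p = 0.000364; adjusted p = 0.739 with an estimated correlation). ITGB4, the beta 4 subunit of the laminin receptor of hemidesmosomes (ENSG00000132470, chromosome 17, 75721328 to 75757818), averaged 331 ± 39.4 TPM in binding and 119 ± 16.3 TPM in non-binding libraries (SD, n = 3 each), a log2 change of 1.47, or 1.11 relative to all genes (SE 0.15; limma, Benjamini-Hochberg adjusted p = 0.00486). ITGA3 changed by 1.05 and TNS3, a tensin that links integrins to actin, by 1.08 on the log2 scale. Genes of cell surface glycosaminoglycans and syndecans included 10 higher and none lower of 24 tested, the same count adjusted over the list alone and 6 with either the common median or quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.0463; adjusted p = 0.739 with an estimated correlation). That call was lost with the common median, with quantile normalization, with rescaling over nuclear protein-coding genes, with the GC trend removed and without any 1 of non-binding replicates 1 and 2 or binding replicates 2 and 3. Without non-binding replicate 3, 1 integrin or focal adhesion gene and none of the glycosaminoglycan genes passed.

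Genes of fatty acid oxidation included 12 higher and none lower of 23 tested, 13 higher adjusted over the list alone, 6 with the common median and 7 with quantile normalization. Their median log2 change was 0.75, or 0.39 above that of all genes (camera with Benjamini-Hochberg, adjusted p = 0.00431; adjusted p = 0.739 with an estimated correlation). ECI1, an isomerase of unsaturated fatty acid breakdown, averaged 59.2 ± 8.24 against 27.0 ± 0.305 TPM (SD, n = 3 each). ETFB, which passes electrons to the respiratory chain, averaged 37.5 ± 3.34 against 20.04 ± 1.10, and ACADVL, the dehydrogenase for very long chains, 214 ± 27.8 against 124 ± 7.06. Lipid droplet and triglyceride storage genes included 10 higher and none lower of 20 tested, the same adjusted over the list alone, 4 with the common median and 6 with quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.0374; adjusted p = 0.739 with an estimated correlation). The lipid droplet call was lost with quantile normalization, with rescaling over nuclear protein-coding genes, with the stricter filter and without any 1 of non-binding replicates 2 and 3 or binding replicate 1. Glycolysis genes included 11 higher and 1 lower of 22 tested, 16 and 1 adjusted over the list alone, 8 and 2 with the common median and 10 and 1 with quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.0197; adjusted p = 0.739 with an estimated correlation). The glycolysis call was also lost with rescaling over nuclear protein-coding genes and with the stricter filter. ENO1 averaged 3162 ± 397 against 1736 ± 60.7 TPM, ALDOC 107 ± 5.89 against 55.5 ± 3.46, and the lactate exporter SLC16A3 189 ± 43.0 against 86.7 ± 2.07 (SD, n = 3 each). No member of these 3 lists passed without non-binding replicate 3.

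FABP4 transcript itself was low in both groups, at 1.64 ± 1.06 TPM in binding and 1.24 ± 1.12 TPM in non-binding libraries (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.647; ENSG00000170323, chromosome 8, 81478419 to 81483263). The FABP4 log2 change of 0.28 turned to -0.04 with the common median, -0.02 with quantile normalization and -0.03 without binding replicate 1. FABP5, the related epidermal carrier, averaged 47.7 ± 4.19 against 54.7 ± 6.66 TPM (adjusted p = 0.352 by limma with Benjamini-Hochberg). CD36, a fatty acid receptor, averaged 0.333 ± 0.0838 against 0.635 ± 0.325 TPM and lay below the filter of 1 TPM in 3 libraries, so it was not tested. Genes of fatty acid binding and uptake included 6 higher and none lower of 19 tested, 9 adjusted over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.0941). Fatty acid synthesis and desaturation included 7 higher of 16, the same over the list alone, and cholesterol synthesis 5 higher of 22, the same over the list alone; neither list passed (camera with Benjamini-Hochberg, adjusted p = 0.105 for each), though fatty acid synthesis did without binding replicate 1. With the common median and with quantile normalization, in that order, higher members numbered 5 and 4 for fatty acid binding (1 and 0 lower), 6 and 6 for fatty acid synthesis (2 and 1 lower) and 0 and 1 for cholesterol synthesis. Without non-binding replicate 3 no member of any of these lists passed. The share of higher cholesterol synthesis genes lay near that of all tested protein-coding genes, 2824 of 12050. With fry, which sets a list against no change, fatty acid binding, fatty acid synthesis and cholesterol synthesis passed upward (adjusted p = 0.0405, 0.014 and 0.0405).

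Of the genes tied to invasion and cell form, MMP1, an interstitial collagenase, was lower in the binding cells at 81.7 ± 17.1 against 135 ± 25.4 TPM (SD, n = 3 each), a log2 change of -0.72, or -1.08 relative to all genes (SE 0.21; limma, Benjamini-Hochberg adjusted p = 0.0387). CDH1, the epithelial cadherin, was lower at 3.43 ± 0.645 against 6.50 ± 0.686 TPM, a log2 change of -0.77, or -1.12 relative to all genes (SE 0.22; limma, Benjamini-Hochberg adjusted p = 0.0387). Both calls were lost when any 1 of the 6 libraries was left out and without a filter, and that of MMP1 with quantile normalization and with the GC trend removed. Genes of epidermal differentiation were also lower (15 of 32 tested, none higher). A fall of CDH1 within MDA-MB-231 cells cannot be told apart here from other cells in the sort, a candidate described below. MMP14, a membrane-bound collagenase, averaged 74.0 ± 8.12 against 58.5 ± 1.26 TPM and the intermediate filament gene VIM 931 ± 74.1 against 830 ± 7.90. The transcription factor gene SNAI2 averaged 11.3 ± 2.88 against 8.97 ± 2.62 and the cytokine gene IL6 4.50 ± 1.92 against 3.54 ± 0.479. These 4 genes did not pass (limma, Benjamini-Hochberg adjusted p = 0.0965, 0.295, 0.378 and 0.552). VIM passed without binding replicate 1 (log2 change 0.23), while with the common median the changes of VIM, SNAI2 and IL6 turned negative (-0.16, -0.01 and -0.09). MMP9 averaged 0.547 ± 0.079 against 0.831 ± 0.504 TPM and was not tested. ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, was also not tested; it was listed at 0, 1.82 and 0.930 TPM in non-binding replicates 1, 2 and 3 and at 0.348, 0.837 and 1.62 TPM in binding replicates 1, 2 and 3. Matrix proteases and their inhibitors included 12 higher and 1 lower of 27 tested, 12 and 2 adjusted over the list alone, 6 and 3 with the common median and 6 and 1 with quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.0524). That list passed with quantile normalization, without a filter and without either non-binding replicate 3 or binding replicate 1. Mesenchymal genes included 8 higher and none lower of 30, the same over the list alone, and genes of invadopodia and actin remodelling 8 higher and 1 lower of 29, the same over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.278 and 0.657). With either the common median or quantile normalization 6 mesenchymal genes were higher, and of the invadopodia genes 1 was higher and 4 lower with the common median and 6 and 0 with quantile normalization. The share of higher mesenchymal and invadopodia genes lay near that of all tested protein-coding genes, 2824 of 12050. Their list medians were -0.01 and -0.31 relative to all genes. With fry, which sets a list against no change, the matrix protease, mesenchymal and invadopodia lists passed upward (adjusted p = 0.0134, 0.014 and 0.0268). Without non-binding replicate 3, 1 matrix protease or inhibitor gene, 1 mesenchymal gene and no invadopodia gene passed.

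Luminal breast markers were higher, 8 of 13 tested with none lower, 9 adjusted over the list alone, 4 with the common median and 5 with quantile normalization. Their median log2 change was 0.92, or 0.56 above that of all genes (camera with Benjamini-Hochberg, adjusted p = 0.0174; adjusted p = 0.739 with an estimated correlation). KRT8 averaged 181 ± 3.16 against 88.9 ± 12.8 TPM, its partner KRT18 298 ± 43.7 against 148 ± 4.15 and KRT19 150 ± 8.08 against 77.5 ± 0.783 (SD, n = 3 each). Basal breast markers split, with 4 of 18 tested higher and 5 lower, 5 and 5 adjusted over the list alone, 3 and 7 with the common median and 3 and 4 with quantile normalization. Their median log2 change was -0.50, or -0.86 relative to all genes (camera with Benjamini-Hochberg, adjusted p = 0.0374; adjusted p = 0.667 with an estimated correlation). The lower members were the stratified epithelial keratins KRT5, KRT6A, KRT14 and KRT17 and TRIM29, and the higher ones included EGFR, CAV1 and the laminin chain LAMB3. These 8 were named after their values were seen. KRT5 and KRT14 are also in the list of epidermal differentiation described below, of which 15 of 32 genes were lower with a median log2 change of -0.84. No luminal or basal marker passed without non-binding replicate 3. The luminal call was lost with the stricter filter. The basal call was lost with the common median, with quantile normalization, with the stricter filter and with fry. It was also lost without any 1 of non-binding replicate 2 or binding replicates 1 and 3. Epithelial genes included 6 higher and 4 lower of 26, 6 and 5 adjusted over the list alone, 5 and 6 with the common median and 5 and 4 with quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.802). Desmosome and junction genes included 3 higher and 6 lower of 23, 5 and 7 over the list alone, 0 and 8 with the common median and 1 and 4 with quantile normalization (camera with Benjamini-Hochberg, adjusted p = 0.085), and that list passed with rescaling over nuclear protein-coding genes and without non-binding replicate 3.

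The largest falls included the keratin genes KRT1 and KRT2 and the histone gene HIST1H2BI. KRT1, a keratin of differentiated epidermis (ENSG00000167768, chromosome 12, 52674736 to 52680407), averaged 692 ± 167 TPM in non-binding and 289 ± 121 TPM in binding libraries (SD, n = 3 each), a log2 change of -1.33, or -1.69 relative to all genes (SE 0.34; limma, Benjamini-Hochberg adjusted p = 0.03). KRT2 averaged 22.3 ± 12.9 against 5.05 ± 1.46 TPM, a change of -1.83. PKP1, a desmosomal plaque gene, averaged 43.9 ± 6.18 against 18.0 ± 3.89 TPM (change -1.25) and CAPNS2, a calpain subunit gene, 4.46 ± 0.594 against 0.742 ± 0.375 TPM (change -1.66). The histone gene HIST1H2BI was at 6.29, 9.07 and 6.95 TPM in non-binding replicates 1, 2 and 3 and at 1.30, 1.56 and 0 in binding replicates 1, 2 and 3. In the same order SPANXB1, a cancer-testis gene, was at 3.41, 3.68 and 5.65 TPM against 0, 1.27 and 1.23, and ENTPD2, an ectonucleotidase gene, at 2.43, 1.97 and 1.68 TPM against 0.565, 0.226 and 0. A list of 32 genes of epidermal differentiation, drawn up after these values were seen and so not tested as a list, had 15 members lower and none higher. Adjusted over the list alone 20 were lower, a count that choosing members after their values were seen can raise. It took 0.741% ± 0.109 of TPM in non-binding and 0.426% ± 0.119 in binding libraries (SD, n = 3 each). Of the genes in this paragraph, PKP1 was lost without non-binding replicate 3, HIST1H2BI, KRT2 and CAPNS2 also without non-binding replicate 2, and KRT1, SPANXB1 and ENTPD2 without any 1 of the 3 non-binding libraries. The ENTPD2 call was lost without binding replicate 2 or 3 as well. Without a filter KRT1 and SPANXB1 were lost, with a pseudocount of 0.1 SPANXB1 and ENTPD2, and with quantile normalization KRT1.

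The largest rises outside the mitochondrial genome were in MUC5B, CAMP, SUSD2, WFDC3 and AQP1. MUC5B, a gel-forming mucin of airway and gland secretions (ENSG00000117983, chromosome 11, 1223066 to 1262172), averaged 15.5 ± 1.08 TPM in binding and 2.18 ± 0.853 TPM in non-binding libraries (SD, n = 3 each), a log2 change of 2.41, or 2.05 relative to all genes (SE 0.24; limma, Benjamini-Hochberg adjusted p = 0.00427). SUSD2, a membrane protein gene, averaged 259 ± 9.53 against 66.8 ± 10.8 TPM (change 1.95) and AQP1, a water channel gene, 6.78 ± 3.04 against 1.17 ± 1.13 TPM (change 1.88). CAMP, which encodes an antimicrobial peptide, was at 0, 0 and 1.18 TPM in non-binding replicates 1, 2 and 3 and at 4.66, 4.80 and 8.49 TPM in binding replicates 1, 2 and 3. WFDC3, a protease inhibitor-like gene, was at 0, 0.359 and 1.10 TPM against 4.13, 3.47 and 5.50 TPM in the same order. The AQP1 call was lost with the common median, with quantile normalization, without a filter and without any 1 of non-binding replicates 2 and 3 or binding replicates 2 and 3, that of CAMP without non-binding replicate 2, and that of WFDC3 without non-binding replicate 2 or 3.

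**Figure D1:**
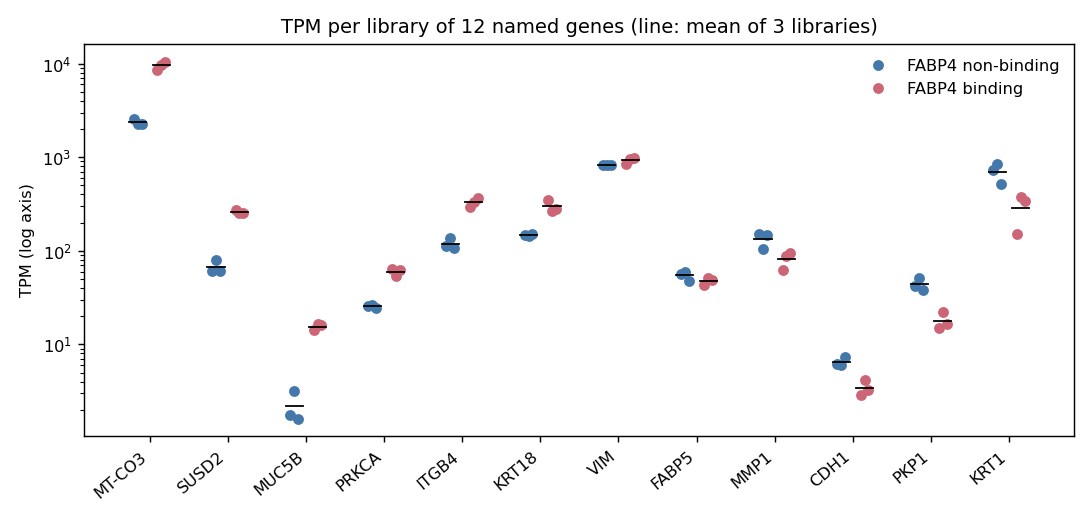
TPM of 12 named genes (log axis) in each of the 3 FABP4 non-binding and 3 FABP4 binding libraries, 1 point per library, with a line at each group mean. MT-CO3, SUSD2, MUC5B, PRKCA, ITGB4 and KRT18 lie higher in all 3 binding libraries, MMP1, CDH1, PKP1 and KRT1 lower, and FABP5 overlaps between the groups.

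Heat shock and chaperone genes included 4 lower and none higher of 22 tested, and none passed when adjusted over the list alone. Of the 22, 7 were lower with the common median and 3 with quantile normalization. Their median log2 change was -0.22, or -0.58 relative to all genes (camera with Benjamini-Hochberg, adjusted p = 0.00431, and adjusted p = 0.667 with an estimated correlation). The call was also lost with quantile normalization and with fry. The mitochondrial co-chaperonin HSPE1 averaged 253 ± 11.8 against 347 ± 16.1 TPM, the HSP90 co-chaperone AHSA1 372 ± 52.1 against 525 ± 23.6, and the small heat shock protein CRYAB 12.4 ± 4.104 against 21.9 ± 1.37 (SD, n = 3 each). Each of these 3 calls was lost without any 1 of the non-binding libraries or binding replicates 2 and 3. Without a filter AHSA1 and CRYAB were lost, and AHSA1 with quantile normalization. Replication-dependent histone genes included 2 higher and 1 lower of 27 tested, 0 and 1 adjusted over the list alone, with 2 lower and none higher under either the common median or quantile normalization. Their median log2 change was -0.22, or -0.58 relative to all genes, but -0.54 with the common median and -0.06 without binding replicate 1 (camera with Benjamini-Hochberg, adjusted p = 0.0174; adjusted p = 0.667 with an estimated correlation). HIST1H2BO averaged 83.2 ± 35.8 against 153 ± 41.6 TPM and HIST2H2AC 69.6 ± 13.3 against 105 ± 31.6 TPM, and neither passed (limma, Benjamini-Hochberg adjusted p = 0.0781 and 0.092), though HIST1H2BO did with rescaling over nuclear protein-coding genes. The histone list was lost with the common median, with quantile normalization, with fry and without binding replicate 1.

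The cell cycle and interferon-stimulated genes that passed were higher, with 1 exception in the G1/S list. Most calls went this way: of 12050 tested protein-coding genes 2824 were higher and 542 lower (limma, Benjamini-Hochberg). The share of higher members in each of the 3 lists lay near or below that background. Median log2 changes were 0.49 for G1/S, 0.52 for G2/M and 0.61 for interferon-stimulated genes, against 0.43 for protein-coding genes. Genes of G1/S and DNA replication included 10 higher and 1 lower of 39 tested, 14 and 1 adjusted over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.0463; adjusted p = 0.796 with an estimated correlation). Genes of G2/M and mitosis included 3 higher of 37, none over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.0369; adjusted p = 0.815 with an estimated correlation). Interferon-stimulated genes included 8 higher of 33, 11 over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.047; adjusted p = 0.739 with an estimated correlation). These 3 calls were lost with the common median, with quantile normalization, with rescaling over nuclear protein-coding genes, with the stricter filter and without either non-binding replicate 2 or binding replicate 1. Only 2 genes of G1/S, none of G2/M and 1 interferon-stimulated gene were higher with the common median, and 4, 1 and 1 with quantile normalization. Without non-binding replicate 3 no gene of these 3 lists passed. The G1/S call was also lost without binding replicate 2 and the interferon call without binding replicate 3. Fry lost the G1/S and G2/M calls as well.

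**Figure D2:**
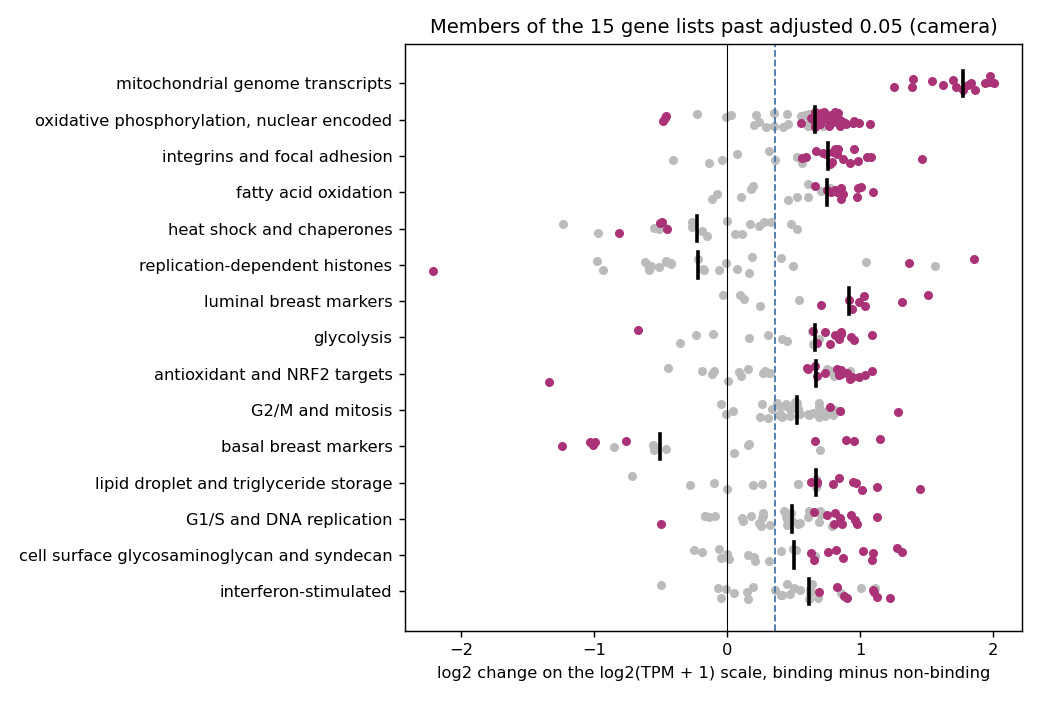
Log2 change, binding minus non-binding, of each tested member of the 15 gene lists past adjusted p 0.05 by camera, 1 point per gene on the log2(TPM + 1) scale, purple where the gene passed limma at 0.05 and grey where it did not. Black bars mark list medians, the solid line 0 and the dashed line the median of all genes at 0.36; the mitochondrial genome stands apart at 1.77.

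The remaining lists did not pass with camera and Benjamini-Hochberg adjustment. Lysosome and endocytosis had 11 of 32 tested genes higher and none lower (13 over the list alone; adjusted p = 0.085), stemness and aldehyde dehydrogenases 8 of 17 (10 over the list alone; adjusted p = 0.133), and ATF4 and unfolded protein response 11 of 28 (the same over the list alone; adjusted p = 0.193). Cytosolic ribosomal proteins had 25 of 50 higher and 3 lower, 29 and 5 adjusted over the list alone (adjusted p = 0.146), which turned to 4 higher and 11 lower with the common median and 29 and 2 with quantile normalization. Hypoxia genes had 5 of 25 higher and 2 lower, 7 and 2 over the list alone, translation and ribosome biogenesis 5 of 29 and 3, with 6 and 3 over the list alone, and IL6 and STAT3 targets 7 of 24 and 1, the same over the list alone (adjusted p = 0.802, 0.804 and 0.802). Targets of NF-kB had 6 of 27 higher (the same over the list alone), p53 targets 2 of 20 and immediate-early genes 3 of 30 (none of either over the list alone), with adjusted p = 0.582, 0.286 and 0.383. Nuclear-retained and long noncoding RNAs had 5 of 11 higher and 1 lower, 6 and 1 over the list alone, and structural RNAs 1 of 8 higher, the same over the list alone (adjusted p = 0.146 and 0.802). Under the common median and quantile normalization, in that order, higher members numbered 6 and 7 for lysosome (2 and 1 lower), 2 and 1 for stemness (1 and 0 lower), 5 and 6 for ATF4 (1 and 0 lower) and 3 and 3 for hypoxia (4 and 3 lower). They numbered 2 and 3 for translation (6 and 2 lower), 3 and 3 for IL6 (2 and 1 lower), 3 and 4 for NF-kB (0 and 1 lower) and 0 and 1 for p53. For immediate-early genes they numbered 0 and 1 (1 and 0 lower), for noncoding RNAs 1 and 2 (1 lower in each) and for structural RNAs 1 and 1. Markers of other cell types did not pass as lists: leukocyte 1 of 12 higher, fibroblast 1 of 9, endothelial 2 of 6 and adipocyte 1 of 7, none lower (adjusted p = 0.0607, 0.205, 0.582 and 0.928), and over the list alone 1, 0, 2 and 1. In the same order 0, 0, 1 and 1 were higher with the common median and 1, 0, 1 and 1 with quantile normalization, with 1 adipocyte gene lower in each. The leukocyte list had a median log2 change of -0.52, or -0.87 relative to all genes, which was -0.13 without binding replicate 1. It passed in the downward direction with rescaling over nuclear protein-coding genes and without any 1 of non-binding replicates 1 and 3 or binding replicate 2. Without a filter 9 lists gained a call: leukocyte, matrix proteases, lysosome, ATF4, cytosolic ribosomal proteins, mesenchymal, cholesterol synthesis, fatty acid synthesis and fatty acid uptake. Cytosolic ribosomal proteins also passed with quantile normalization. Fry, which sets a list against no change, called the lysosome, stemness, p53, IL6, noncoding RNA, structural RNA and endothelial lists upward, as given below. Camera sets a list against all other genes, so 6 lists with a positive median below 0.36 had a downward direction: desmosome and junction, immediate-early, NADPH oxidase, invadopodia, epithelial and adipocyte. Without binding replicate 1 that direction turned up for the NADPH oxidase, epithelial and adipocyte lists, and for the adipocyte list also without non-binding replicate 3 and with the common median.

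The makeup of the libraries differed between the groups beside each gene group above. Processed pseudogenes, copies of messenger RNAs inserted back into the genome, took 25.8% ± 1.71 of TPM in non-binding and 15.4% ± 3.37 in binding libraries (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest possible). Of 1863 tested, 24 were higher and 514 lower in the binding libraries, with a median log2 change of -0.64. The 12050 tested protein-coding genes had 2824 higher and 542 lower with a median of 0.43 (limma, Benjamini-Hochberg). EEF1A1P5, a copy of the elongation factor gene EEF1A1, was the highest gene in all 6 libraries, at 1.44% to 3.95% of TPM. How the counting shared reads between a gene and its near-identical copies is not given in the sources used here, so levels of genes with many copies are uncertain. Pearson correlations of log2(TPM + 1) were 0.951 to 0.970 within the binding group, 0.951 to 0.960 within the non-binding group and 0.895 to 0.950 between groups. Binding replicate 1 lay farthest out on the first principal component (50.9% of variance), at 73.1 against 23.4 and 26.7 for binding replicates 2 and 3, and had the lowest pseudogene share, 11.6% against 17.6% and 17.1%.

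**Figure D3:**
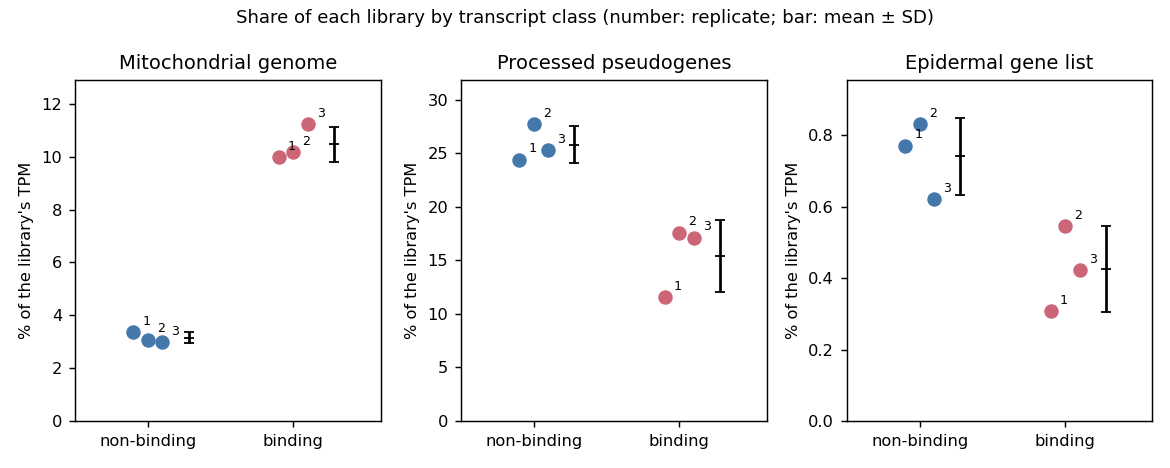
Share of each library's TPM (%) from the mitochondrial genome, processed pseudogenes and a list of 32 epidermal genes, 1 point per library numbered by replicate, with the mean and SD of each group of 3 as a bar. The mitochondrial share lies between 2.98% and 3.38% in non-binding and between 9.99% and 11.2% in binding libraries; the other 2 shares are lower in the binding libraries.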

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

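The common median, the rescaling over nuclear protein-coding genes, the removal of the GC trend and the pseudocount for library similarity were chosen after seeing the data. The count of 4156 genes (3047 higher, 1109 lower) became 2443 with quantile normalization (1197 higher), 1873 without a filter (1373 higher, 500 lower) and 1033 at 2-fold (720 and 313), and the common median gave 962 higher and 1890 lower. Leaving out 1 library gave 64 to 2863 genes, 58 to 1975 higher and 6 to 888 lower; with fewer libraries the test has fewer residual degrees of freedom, and the cause of the differences between libraries was not tested. The count of 15 lists became 9 with quantile normalization, the common median or rescaling, 24 without a filter and 8 with the stricter filter. It was 0 with an estimated correlation and 26 with fry, and 8 to 17 when a library was left out. With rescaling the mitochondrial, noncoding RNA and structural RNA lists had 0 tested genes, so the mitochondrial call is missing there by construction. Fry lost 5 of the 15 calls: heat shock (adjusted p = 0.13), histones (0.228), G2/M (0.166), G1/S (0.0873) and basal markers (0.0874). Fry gained 13 calls, all upward. They were fatty acid binding (adjusted p = 0.0405), fatty acid synthesis (0.014), cholesterol synthesis (0.0405), protein kinase C (0.027), matrix proteases (0.0134) and mesenchymal (0.014). The others were IL6 and STAT3 targets (0.0111), stemness (0.0157), lysosome (0.0243), p53 (0.033), noncoding RNA (0.0405), structural RNA (0.033) and endothelial markers (0.0268). The 26 also include the 3 lists whose direction it turned. Fry turned the direction of the epithelial (adjusted p = 0.033), invadopodia (adjusted p = 0.0268) and adipocyte (adjusted p = 0.0405) lists to up, since it sets a list against no change and not against other genes. Over all alternatives the adjusted p of these 3 lists lay between 0.033 and 0.978, 0.0268 and 0.932, and 0.0405 and 0.982. The mean within-group correlation was 0.957, or 0.899 with a pseudocount of 0.1. Of 49 named genes tested, none changed direction while past the threshold; without non-binding replicate 3, 30 lost their call, and without non-binding replicate 2, 20. The calls lost without non-binding replicate 3 had adjusted p from 0.0516 (PRKCA) to 0.136 (AKR1B10) by limma, so many fell just past the threshold.

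The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.035, -0.017 and 0.028, and only number 1 correlated best with its own. With the number as a block, 4306 genes passed (3174 higher, 1132 lower), the glycosaminoglycan and interferon lists and the genes AKR1B10 and CDH1 lost their calls, and the leukocyte list gained one. DESeq2, voom, total-count and size-factor alternatives were not run because the values are TPM. The depth behind each value is unknown, so what depth limits cannot be stated.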

Other observations

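The 4 lists in this part and the tests of explanations in it were chosen after the values were seen, while the main limma fit and the fits without 1 library were planned. The counts therefore describe the genes in the lists and no list test is given. Counts adjusted over these lists alone carry the same choice of genes and are no added evidence. Of 8 keratin genes in the list of simple epithelial, hair and other keratins, 6 were higher in the binding cells and 1 lower by limma. The counts were the same adjusted over the list alone, and the median log2 change was 1.01. The list does not hold every keratin: the basal markers KRT6A and KRT17, which were lower, are not in it. The 8 included the simple epithelial keratins KRT7, KRT8, KRT18 and KRT19 and the hair keratins KRT81 and KRT86. KRT81 averaged 2172 ± 669 TPM in binding and 919 ± 58.0 TPM in non-binding libraries, KRT7 555 ± 182 against 232 ± 15.1, and KRT86 33.1 ± 10.5 against 10.4 ± 2.40 (SD, n = 3 each), while KRT23 was lower at 18.1 ± 0.813 against 30.9 ± 7.50. Of 13 laminin and hemidesmosome genes, 8 were higher and 1 lower, the same adjusted over the list alone and 7 and 1 with either the common median or quantile normalization, with a median log2 change of 0.79. LAMA5, the alpha 5 laminin chain, averaged 88.6 ± 3.68 against 31.4 ± 1.51 TPM, LAMB2 145 ± 24.9 against 64.2 ± 1.81, and the cytolinker PLEC 210 ± 26.9 against 97.1 ± 9.91. The lower member was COL17A1, a collagen of epidermal hemidesmosomes, at 6.35 ± 0.855 against 16.6 ± 3.05 TPM. Without non-binding replicate 3, no keratin of that list and 2 of the 13 laminin and hemidesmosome genes passed.

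The list of mucins and secreted barrier proteins held 11 genes, of which 6 were tested. By limma 5 were higher and none lower, or 5 and 1 adjusted over the list alone, and 3 and 1 with either the common median or quantile normalization. The median log2 change was 1.43. MUC5AC averaged 8.48 ± 3.27 TPM in binding and 2.48 ± 2.03 TPM in non-binding libraries, the trefoil factor TFF3 35.0 ± 5.12 against 13.6 ± 3.72, and PSCA 7.71 ± 0.550 against 1.75 ± 0.679 (SD, n = 3 each). Of the 6, 3 were higher without binding replicate 1 and 1 without non-binding replicate 3. Epidermal keratins ran the other way: KRT10 was at 553 ± 123 against 1189 ± 194 TPM, KRT14 at 388 ± 68.6 against 781 ± 143 and KRT5 at 139 ± 20.3 against 332 ± 73.3. The epidermal list had a median log2 change of -0.84, and without non-binding replicate 3 none of its 32 genes passed.

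Of 1863 tested processed pseudogenes, 514 were lower in the binding libraries, 24 higher and 1325 not past the threshold by limma, while the median log2 change of the parent genes was 0.24. If human reads were shared between a parent and its copies at a fixed ratio, both would change alike, but over 1174 pairs from 462 parents the pseudogene's log2 change minus its parent's had a median of -0.77 (95% bootstrap interval -0.85 to -0.68), which argues against it. RNA of another mammal aligned to the human genome, with a larger share in the non-binding libraries, may add reads to intronless copies. It stays open: across protein-coding genes the partial Spearman correlation of log2 change with UTR share, given GC content and level, was 0.0727 (0.0443 to 0.101), short of the 0.1 set for it and above 0. A difference in RNA handling or in the biology of the sorted cells was not tested.

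KRT1 was at 151 to 840 TPM in all 6 libraries of a breast cancer line, and 15 of the 32 genes of epidermal differentiation were lower in the binding group and 17 not past the threshold. Human cells of another type in the sort, keratinocytes among them, are a candidate explanation. The added list cannot test this, since it was drawn up after the values were seen. The genes of the epidermal differentiation complex were therefore taken by position (chromosome 1, 152084144 to 153262122). This region too was chosen after epidermal genes were seen to be lower. Its genes may change together, so they are not independent of each other or of the list. Of 32 tested there, 93.8% had a negative log2 change, against 31.9% of all tested genes, 9 passed as lower and none as higher, and 7 were also in the added list (of the other 25, 23 were negative). The sort by FABP4 binding does not by itself remove such cells, and the test does not part them from MDA-MB-231 cells that express these genes, such as CRCT1 at 556 ± 132 TPM in non-binding and 318 ± 76.3 TPM in binding libraries (SD, n = 3 each).

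The rise of mitochondrial transcripts was set against composition and base content. Dilution by a second RNA component that is smaller in the binding libraries would raise alike all cell line transcripts that the component lacks. Nuclear genes that it also supplies would rise less. The median of the 13 mitochondrial messenger RNAs exceeded the 99th percentile of 4687 nuclear protein-coding genes at 20 TPM or more by 0.55 log2. The SD among the 13, which is not a spread between libraries, was 0.20. The gap argues against a component that lacks most nuclear transcripts of the cell line as the whole cause. A component that supplies most nuclear transcripts but few mitochondrial ones could leave such a gap and was not tested. GC content is argued against too, since 1473 nuclear genes in the same GC range had a median log2 change of 0.15. A higher mitochondrial RNA content of FABP4-binding cells may stand behind the rise and stays open, as does an untested difference in cell state at sorting.

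With a common median, 33.7% of calls were higher in the binding libraries, against 73.3% without it. With a median log2 change above 0 such a shift lowers that share by construction, so it does not tell whether a change of composition underlies the excess of higher genes. With TPM rescaled over nuclear protein-coding genes, 3723 genes were higher and 878 lower, or 80.9% higher. That argues against the mitochondrial and pseudogene shares as the cause of the excess among these genes. A change of composition within these genes stays open. The real split of the 6 libraries called 4156 genes and the highest of the other splits called 4. With 10 splits, of which 1 called as many, the share cannot fall below 0.1.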
